A study of Rattus norvegicus with 10 samples.

How the data were processed

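Liver RNA from 10 male Sprague-Dawley rats, an outbred laboratory strain, was measured on Affymetrix 3' expression arrays, with 5 control animals and 5 animals exposed to effluent from factories that make bulk drugs. The labels describe 10 rats, so each array stands for 1 animal. The p-values per probe set and of list scores rest on the spread between animals. The labels give neither the dose nor the length of the exposure.

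The deposited values are log2 expression values per probe set, summarised by the authors with RMA in R 2.8.1, per the submitters' processing notes. RMA corrects the background and normalizes the arrays to one another at the probe level, so a shift shared by most genes of an array is removed before the values are formed. The log2 scale was read from the values, which lie between 2.19 and 15.0. The scanner files and the version of the array's probe annotation used by the authors were not used here. Medians per array lay between 5.43 and 5.50, and any pair of arrays correlated between 0.991 and 0.996 across probe sets. No pair of arrays held the same values. The number of arrays limits the precision of each value.

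Of 31099 probe sets, 57 Affymetrix control sets were left out and 31042 were tested. Gene names came from the platform annotation, with 20826 probe sets naming 1 gene, 436 naming several and 9780 unnamed here. Of the named ones, 20758 were found by Entrez gene number in a RefSeq gene table for assembly GRCr8, and 0 symbols changed. No gene was named from a probe set with several symbols. Each of 14217 genes was represented in gene lists by its probe set with the highest mean over all arrays.

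Exposed and control animals were compared per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Differences are exposed minus control on the log2 scale. Standard errors and 95% intervals come from the same fit. Altogether 34 gene lists, covering pathways, cell types and signs of tissue handling, were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists. Camera sets list genes against other genes. At the preset it takes the genes of a list as nearly independent, so its p-values do not measure how a list varies between animals. The lists held 678 entries, of which 600 were measured. Camera was repeated with a correlation estimated for each list, and limma's fry tested whether a list moved on balance one way. A list score was formed per animal as the mean over the list's genes of each value minus that gene's mean over the 10 arrays. The difference in score between groups was tested with a two-sided exact permutation test, whose smallest possible p is 0.00794. Intervals of score differences assume normal values with equal spread. The ratio of 3' to 5' control sets for Gapdh and beta-actin was taken as a sign of RNA quality per array and tested in the same way.

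The comparison, its tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 10 genes with the largest change in each direction past the threshold. Where fewer pass, it fills 8 places per direction by the smallest p and names these as not past the threshold. It always takes 13 genes of drug metabolism, liver function and stress, and up to 3 members of each list with the smallest p. Any of the 13 genes without a probe set naming it alone, such as Cyp2b1, was not analysed here. Genes named outside the rule are marked as chosen after their values were seen.

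The tests were checked on 20 simulated data sets, each with 200 probe sets changed among 31042. Simulated values had the means of these probe sets and the variances of the limma fit. As eBayes draws those variances towards a common value, simulated spreads differed less between probe sets than the real ones. Among 50 probe sets per size, 92.2% of 1.5-fold changes, 99.0% of 2-fold changes and 99.6% of 3-fold changes were called, with 9.80 false calls per data set on average. The adjustment is stricter where fewer probe sets change, so these shares hold for this number of changes, for these variances and for independent noise. In the real data a 1.56-fold difference of Mx2 was not called. A list of interferon-stimulated genes shifted by 0.20 on the log2 scale was called in 20 of 20 data sets, with independent genes. The alternatives covered a filter on low values, centring, quantile normalization, a block on the replicate number, array weights, a trended and robust prior, the RNA quality ratio as a covariate and leaving out each array. For lists they also covered estimated correlation, fry and all probe sets of each gene. Correlations between genes across animals were computed on values with group means removed, with 100000 permutations, or every order where 7 animals were used, and Benjamini-Hochberg adjustment over the 4 relations tested on all animals. Correlations with RNA quality and between probe sets of a gene used the values as deposited.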

Results

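Liver expression was measured in 10 male rats, 5 control animals and 5 exposed for a short time to effluent from bulk drug factories. The arrays resembled one another, with a median correlation of 0.994 within a group and 0.994 between groups. The median probe set varied between animals of a group with an SD of 0.13 on the log2 scale.

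The comparison of exposed with control livers addresses whether the effluent altered gene expression in liver. Exposed livers had higher values for 22 of 24 measured interferon-stimulated genes, the antiviral and antigen-presenting genes switched on by interferons, with a mean difference of 0.21 on the log2 scale. They had lower values for 14 of 16 heat shock genes, the chaperones of protein folding, with a mean difference of -0.14. Genes of fatty acid synthesis were higher for 18 of 22 members and lymphocyte markers for 12 of 14. Camera called these 4 lists at its preset correlation, but 0 lists passed with an estimated correlation, with fry or with list scores. At least as many lists were called in 73 of 100 splits of the animals, the real one included. Lists that were not called could be as one-sided, such as Kupffer cell and macrophage markers (11 of 12 higher) and PPAR-alpha genes (26 of 31 lower). No single gene passed the test, drug-metabolising enzymes and markers of liver function included.

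Across 31042 probe sets, limma called 0 at an adjusted p of 0.05, with a smallest adjusted p of 0.879. At an unadjusted p under 0.05 there were 1695 probe sets, 952 higher and 743 lower in exposed livers, against 1552 given by chance. The 2 groups did not overlap for 277 probe sets (0.892%), where chance gives 246 (0.794%). The 95% interval excluded a 2-fold change either way for 99.5% of probe sets and a 1.5-fold change for 97.3%. These shares take in all probe sets, and which of them were too dim to measure is unknown.

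The genes with the smallest p values among those higher in exposed livers, none past the threshold, were led by Mx2, an interferon-induced GTPase. Its value went from 6.65 ± 0.14 in controls to 7.30 ± 0.22 in exposed animals (SD, n = 5 each), a difference of 0.64 ± 0.10 (SE) or 1.56-fold, with a limma adjusted p of 0.879. Evl, a regulator of actin filaments, differed by 0.33 ± 0.06, Adora1, the adenosine A1 receptor, by 0.45 ± 0.10 and Lepr, the leptin receptor, by 0.28 ± 0.06. Fbxl8, Bex3, Ferry3 and C10h5orf47 completed the group, with differences between 0.27 and 0.38. Among those lower in exposed livers, Sephs2, which makes the selenium donor for selenoproteins, differed by -0.47 ± 0.09 and Nceh1, a cholesteryl ester hydrolase, by -0.55 ± 0.13. Hacd1, Taf13, Sgms1, Psme4, Naa25 and Usp20 followed, with differences between -0.34 and -0.24. All 16 genes had an adjusted p of 0.879.

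Other probe sets of a gene did not always follow. The arrays hold a pair of probe sets for Mx2, and the other, chosen after its values were seen, went the opposite way. It read 6.39 ± 0.19 in controls and 4.98 ± 1.02 in exposed animals (SD, n = 5 each), a difference of -1.41 ± 0.37 (SE) with a limma adjusted p of 0.879. Exposed animal 1 read 6.75 on it, above the controls at 6.25 to 6.69, and the other exposed animals read 4.21 to 4.88. Without exposed animal 1 this probe set passed the test over all probe sets, at a difference of -1.85 and a limma adjusted p of 0.000661. For Ferry3 and Sgms1, 1 of 2 probe sets had the sign given above, for Usp20 2 of 3 and for Lepr 6 of 7.

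**Figure D1:**
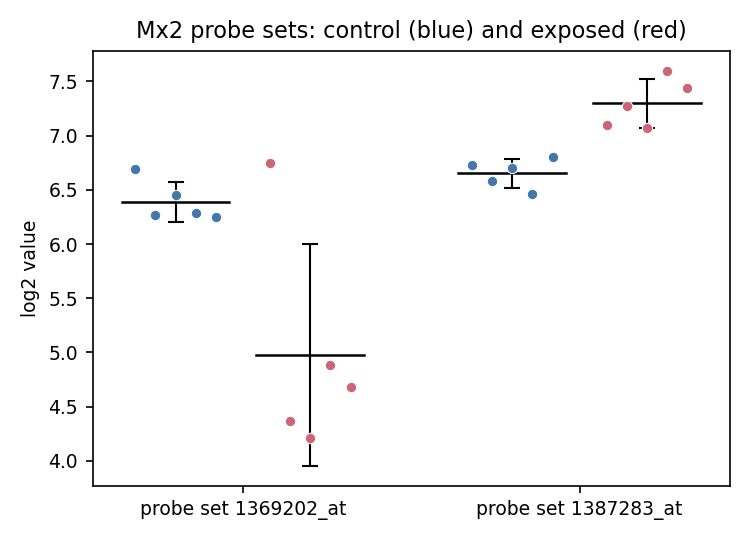
Log2 values of the Mx2 probe sets, 1 point per animal, with control animals in blue and exposed animals in red. Horizontal lines are group means and bars are SDs (n = 5). On the right all exposed animals, from 7.07 to 7.60, lie above all controls, while on the left 4 exposed animals lie at 4.21 to 4.88 and the remaining one reads 6.75.

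Enzymes that liver induces on contact with foreign compounds showed no call. Cyp1a1, induced through the aryl hydrocarbon receptor, differed by 0.02 (95% interval -0.23 to 0.26) and Cyp1a2 by -0.23 (-0.49 to 0.03). Cyp3a23-3a1, induced through the pregnane X receptor, differed by -0.21 (-0.46 to 0.04), and Cyp3a2 by 0.03 (-0.09 to 0.15). Cyp2c11, a male-predominant enzyme, differed by 0.05 (-0.05 to 0.16), Cyp4a1, a target of PPAR-alpha, by -0.10 (-0.64 to 0.43) and Car3 by 0.02 (-0.10 to 0.13). Albumin (Alb) differed by 0.00 (-0.11 to 0.10). Cdkn1a, a target of p53, differed by -0.25 (-0.55 to 0.04). The intervals were wide for Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -0.19 (-1.77 to 1.39), and for the oxidoreductase Nqo1 at 0.36 (-0.76 to 1.49). Limma adjusted p values of these genes were between 0.880 and 0.995. Leaving out 1 array moved each of these differences except that of Cyp2c11 by over 1.5 times or in sign, such as Cyp3a23-3a1 to -0.099 without control animal 5 and Cyp1a2 to -0.12 without exposed animal 5.

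With camera at its preset correlation, 4 of 34 lists passed an adjusted p of 0.05, of which 3 were higher and 1 was lower in exposed livers. With an estimated correlation 0 lists passed, and camera then gave 2 at an unadjusted p under 0.05. Against the preset 0.01, the estimates were 0.0784 for interferon-stimulated, 0.139 for heat shock, 0.155 for fatty acid synthesis and 0.445 for lymphocyte genes. The fry test likewise called 0 lists, with 2 at an unadjusted p under 0.05, and so did the exact permutation test of list scores, also with 2. In 73 of 100 splits of the 10 animals, the real one included, camera called at least 4 lists, and its count was 2 without control animal 4 and 7 without control animal 3.

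Interferon-stimulated genes rose as a list (camera adjusted p = 9.38e-09). The call was lost at an adjusted p = 0.104 with an estimated correlation. Of the 24 members, 0 passed over all probe sets and 1 passed adjusted over the list alone (adjusted p 0.00101). This was Mx2, whose other probe set went the opposite way, and the arrays do not show which of the pair follows its transcript. Unadjusted p values under 0.05 were given by 8 members, all of them higher in exposed livers. Cxcl10, a chemokine that draws T cells, differed by 0.32 ± 0.10 (SE) and Mx1 by 0.38 ± 0.12. The list score was -0.10 ± 0.04 in controls and 0.10 ± 0.11 in exposed animals (SD, n = 5 each), a difference of 0.21 with a 95% interval of 0.09 to 0.33. The exact permutation p was 0.00794, the smallest possible, and 0.270 after adjustment over the lists. Markers of lymphocytes moved the same way, as given below.

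**Figure D2:**
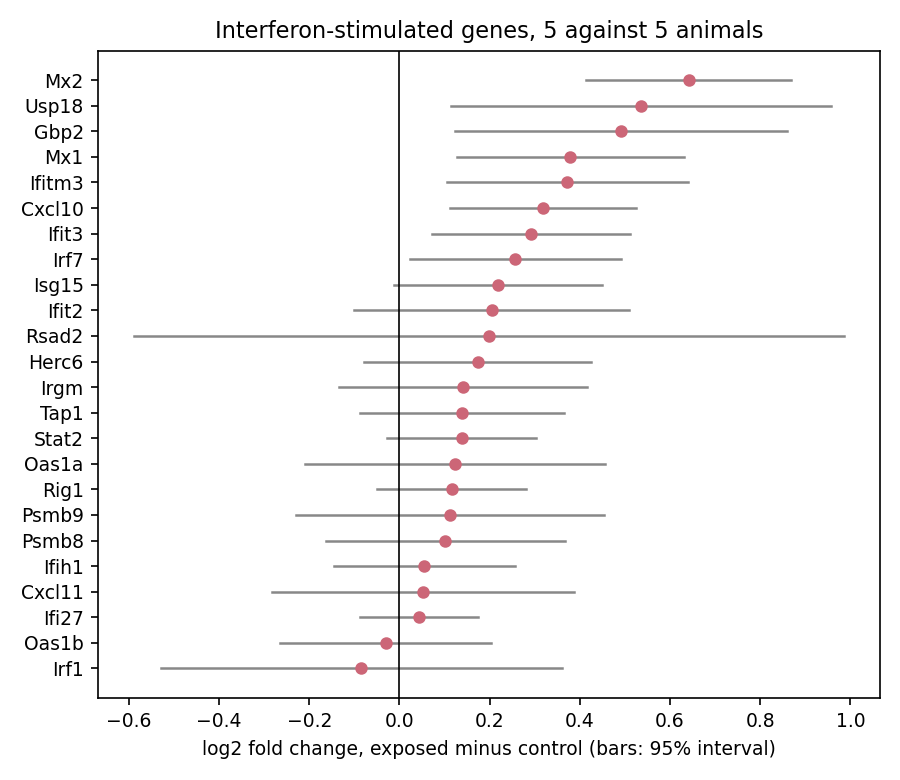
Differences in log2 value between 5 exposed and 5 control animals for the 24 measured interferon-stimulated genes, with points for the estimates and bars for 95% intervals. The estimates lie above 0 for 22 genes, and the intervals exclude 0 for 8.

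Heat shock genes fell as a list (camera adjusted p = 1.43e-04), with an adjusted p = 0.446 with an estimated correlation. None of the 16 members passed, with 0 adjusted over all probe sets and 0 adjusted over the list alone, and limma gave 4 at an unadjusted p under 0.05. Hspb1, a small heat shock protein, differed by -0.49 ± 0.16 (SE), Hsph1 by -0.35 ± 0.13 and the chaperone Hsp90ab1 by -0.18 ± 0.07. Hspa1a, the inducible Hsp70, chosen after its values were seen, differed by -0.07 ± 0.08. The list score was 0.07 ± 0.08 in controls and -0.07 ± 0.08 in exposed animals (SD, n = 5 each; exact permutation p 0.0317, adjusted 0.540).

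Genes of fatty acid synthesis rose as a list (camera adjusted p = 5.82e-03), with an adjusted p = 0.860 with an estimated correlation. Of 22 members limma called 0 over all probe sets and 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05 that went opposite ways. Acly, which supplies acetyl-CoA for lipid synthesis, differed by 0.32 ± 0.14 (SE) and Lpin1, a phosphatidate phosphatase, by -0.38 ± 0.17. Pnpla3, a lipid droplet protein, differed by 0.87 ± 0.41, with all 3 of its probe sets higher, but by 0.48 without exposed animal 1. Without control animal 1 Lpin1 differed by -0.24. The exact permutation p of the list score was 0.0952. The call was also lost without control animal 4 (adjusted p 0.0859) and without exposed animal 3 (0.0753).

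Among markers of other cells, lymphocyte markers rose as a list (camera adjusted p = 0.0460), with an adjusted p = 0.860 with an estimated correlation. Cd3d, a part of the T cell receptor complex, differed by 0.20 ± 0.09 (SE), Cd52 by 0.29 ± 0.16 (0.16 without control animal 4) and Nkg7 by 0.14 ± 0.10 (0.084 without exposed animal 2). Of 14 members 0 passed over all probe sets and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05 by limma. The exact permutation p of the list score was 0.278. The call was lost at an adjusted p of 0.580 with RNA quality as a covariate and at 0.213 with quantile normalization. Leaving out single arrays ended it for control animals 4 (0.439) and 5 (0.392) and for exposed animals 1 (0.196), 2 (0.292), 4 (0.0868) and 5 (0.0902). Only 4 of the 14 markers passed the filter on low values, a mean above that of the median probe set. Lists needed at least 5 genes, so this one was not tested under the filter.

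**Figure D3:**
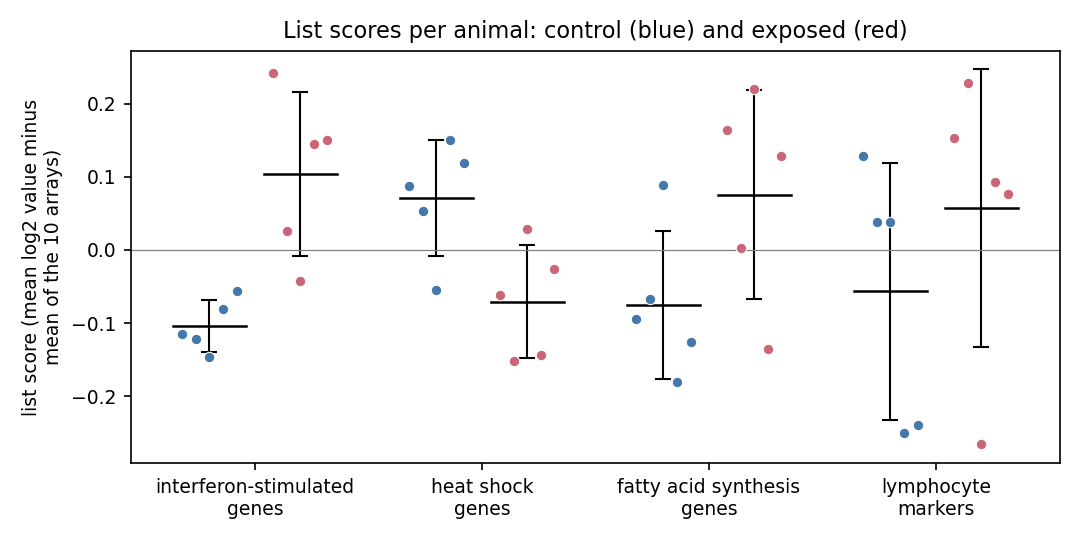
List scores of the 4 lists past the camera threshold, 1 point per animal, with control animals in blue and exposed animals in red. Scores are mean log2 values relative to the mean of the 10 arrays, horizontal lines are group means and bars are SDs (n = 5). The interferon scores lie between -0.15 and -0.06 in controls and above them, between -0.04 and 0.24, in exposed animals, and the groups overlap for the other lists.

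The remaining 30 lists did not pass camera, with adjusted p values between 0.140 and 0.972. Kupffer cell and macrophage markers were higher for 11 of 12 members (mean 0.17, adjusted p 0.140), with Aif1 at 0.34 ± 0.26 (SE) and Cd5l at 0.36 ± 0.29. Without control animal 5 Aif1 differed by 0.13, Cd5l by 0.16 and the list mean was -0.00039, while the mean was 0.093 without exposed animal 2 and 0.31 without exposed animal 3. Genes of PPAR-alpha and fatty acid oxidation were lower for 26 of 31 (mean -0.08, adjusted p 0.140), with a mean of 0.0017 without control animal 5 and -0.16 without control animal 2. Gluconeogenesis and fasting genes had an adjusted p of 0.329, with Sds, which degrades serine, at -0.55 ± 0.19. Among lists on foreign compounds and their damage, camera gave an adjusted p of 0.508 for AhR targets, 0.700 for CAR and PXR targets, 0.539 for phase II conjugation enzymes, 0.508 for NRF2 targets and 0.695 for p53 targets. The phase II enzymes Glyat and Gstm3 differed by -0.35 ± 0.11 and -0.54 ± 0.18. Adjusted p values were 0.411 for acute phase genes, with Stat3 at -0.31 ± 0.10, and 0.640 for both cholesterol synthesis and endoplasmic reticulum stress. Limma called 0 of the 574 list genes over all probe sets.

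A difference in RNA quality between the groups did not pass the test. The 3' to 5' log2 ratio, averaged over Gapdh and beta-actin, was 0.61 ± 0.08 in controls and 0.56 ± 0.04 in exposed animals (SD, n = 5 each; exact permutation p 0.278). Control animal 5 had the highest ratio, 0.735, with the other arrays at 0.494 to 0.626. Without this same animal the means were -0.00039 for Kupffer cell markers and 0.0017 for PPAR-alpha genes, as given above. Immediate early genes, which respond to handling of tissue within minutes, had a camera adjusted p of 0.411, with Atf3 at 0.30 ± 0.13 (SE), or 0.185 without exposed animal 4, and Dusp1 at 0.52 ± 0.26.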

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

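The splits with an estimated correlation were run after the counts at the preset correlation were seen, and the interferon list was picked for weighing because it had the smallest camera p.

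The higher interferon-stimulated genes of exposed livers were set against technical explanations. A higher share of macrophages and lymphocytes is argued against as the whole cause, since the score difference of 0.208 was 0.203 with a leukocyte marker score as a covariate (permutation p 0.0159). The fit takes a common slope for both groups. Exposed animal 3 had the lowest macrophage, lymphocyte and interferon scores of its group. Control animal 5 had the lowest macrophage but the highest interferon score of its group. A part played by these cells is therefore not excluded. RNA quality is argued against by the same kind of fit, with 0.204 left (permutation p 0.0159). The score difference does not rest on 1 animal, as it stayed between 0.173 and 0.244 without each array in turn. The exact permutation p values, up to 0.0159, add no support. The scores of the 2 groups did not overlap, which held these p values to that bound in advance. Clock phase was not among the explanations weighed. With the clock gene Dbp as a covariate, chosen after the values were seen, the list mean was 0.199. Camera then gave an adjusted p of 1.15e-06 at the preset correlation and 0.323 with an estimated one. Chance stays open, because 21 of 100 splits of the animals gave some list a p as small as the real 2.76e-10, the smallest being 2.17e-15, so an effect of the effluent remains a hypothesis that may not hold. The interferon list itself reached so small a p in 1 of the 100 splits, the real one, but it had been picked for its small p.

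The other counts were set against splits of the same 10 animals. The real split gave 0 probe sets past the threshold, which all 100 splits reached by definition, and 12 of the others gave at least 1, with 5 as the highest. The 1695 probe sets at an unadjusted p under 0.05 were matched by 30 of 100 splits, the highest other reaching 3293, so chance is not excluded. The 4 lists past the threshold were matched by 73 of 100 splits, with 12 as the highest of the others and 5 as the median. With camera's estimated correlation, the real split gave 0 lists past the threshold and 1 of the others gave 1.

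Single animals stood apart from the rest of their group, by the gap to the nearest animal over the range of the group, in 18 of 312 groups of named values, where 1 in 20, or about 16, is given by chance. Exposed animal 4 read 6.62 for Cxcl10 (others 6.14 to 6.25), 5.42 for the chemokine Ccl2 (4.44 to 4.65), 10.95 for Acly (11.48 to 11.56), 11.16 for Eci2 (10.98 to 11.03) and 9.40 for Psme4 (9.48 to 9.49). Exposed animal 3 read 6.51 for Bex3 (6.63 to 6.65), 10.11 for the Kupffer cell lectin Clec4f (10.81 to 10.95) and 6.71 for Cfd (7.21 to 7.30). Exposed animal 2 read 5.90 for the chaperone Hyou1 (7.71 to 8.38) and 11.96 for Cyp27a1 (11.53 to 11.62). It also scored -0.190 for bile acid and sterol transport genes (0.0116 to 0.0566) and 0.257 for bile duct cell markers (-0.0971 to -0.00848). Exposed animal 1 read 4.52 for Cd3d (4.73 to 4.81). Among controls, animal 1 read 11.14 for Fmo1 (11.51 to 11.65) and 3.78 for Pnliprp1 (3.47 to 3.52), and animal 3 read 9.19 for Glyat (9.34 to 9.37). Control animal 4 read 8.18 for Lcn2 (6.77 to 7.12) and scored -0.0796 for skeletal muscle markers (-0.00956 to 0.0188).

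Genes chosen after their values were seen, for their spread or for probe sets that disagree, gave 6 such animals in 32 groups. Exposed animal 1 read 6.75 on the second Mx2 probe set (others 4.21 to 4.88), and what each Mx2 probe set detects was not tested, as probe sequences were not used here. Control animal 3 read 5.34 and exposed animal 5 read 5.23 for RT1-A, a class I histocompatibility gene, against 7.97 to 8.44 and 7.57 to 8.02 in the others. Control animal 2 read 7.90 on a probe set of RT1-Bb (3.75 to 4.74), control animal 5 read 8.44 on a probe set of Onecut1 (6.14 to 6.80) and exposed animal 4 read 3.81 on a probe set of Abhd3 (7.19 to 7.53).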

How the results depend on the processing

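Alternatives with Dbp as a covariate or without Mx2 were chosen after seeing the data. The others were planned. The count of 0 probe sets past the threshold held except without exposed animal 1 (leave-one-out 0 to 1). There the second Mx2 probe set passed. The count of 4 lists became 0 with camera's estimated correlation, with fry and with Dbp plus estimated correlation. Leave-one-out gave 2 (without control animal 4) to 7 (without control animal 3). The mean differences of 0.21 for interferon-stimulated, -0.14 for heat shock, 0.15 for fatty acid synthesis and 0.11 for lymphocyte genes fell short of the threshold with both estimated correlation and fry, which allow for genes that move together. Fatty acid synthesis genes lay at 0.12 to 0.20 over leave-one-out, past the threshold in 8 of 10. Lymphocyte markers also lost their camera call with quantile normalization (mean 0.0931, adjusted p 0.213) and with the RNA quality covariate (mean 0.0460, adjusted p 0.580). Their mean lay at 0.0651 to 0.194 over leave-one-out, past the threshold in 4 of 10, and the cause was not tested. Interferon and heat shock lists kept their calls under 20 of 22 and 19 of 21 alternatives. Dbp with estimated correlation, not counted here, ended both (adjusted p 0.323 and 0.441). With that fit left aside as well, adjusted p values ran from 2.11e-11 to 0.104 for interferon, 2.56e-06 to 0.446 for heat shock, 2.97e-05 to 0.873 for fatty acid synthesis and 6.28e-05 to 0.873 for lymphocyte lists. Without Mx2 the interferon mean was 0.19 (adjusted p 3.39e-07).

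Among the other lists, Kupffer cell and macrophage markers passed under 7 alternatives, including without control animals 1, 2 or 3 or exposed animal 3 (adjusted p values 9.58e-05 to 0.935 over all alternatives), and PPAR-alpha genes under 4, including without control animals 2 or 3 or exposed animal 4 (3.88e-04 to 0.981). Without control animal 5 their means were -0.00039 and 0.0017, and over leave-one-out they ran to 0.31 and -0.16. Under 1 alternative each passed cell cycle genes without control animal 1 (mean 0.159, adjusted p 4.60e-06, others up to 0.99), stellate cell markers without control animal 3 (0.113, 0.00732, up to 0.873) and gluconeogenesis genes without exposed animal 3 (-0.127, 0.0403, up to 0.873). Among values not past the threshold, which have no called direction, the sign changed under some alternative for 21 of 30 lists, 0 of 16 genes with the smallest p and 7 of 105 other named genes. The 16 genes were picked for a small p in these same arrays, which made a change of sign unlikely, so their count does not show stability. Leaving out 1 array moved the difference by over 1.5 times or in sign for 68 of the 121 named genes, none of which passed. List scores gave 0 calls under every alternative, and RNA quality did not pass with Gapdh or beta-actin alone.

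Replicate numbers occur in both groups. Over all probe sets the residual correlations of same-numbered animals were 0.094, 0.022, -0.070, -0.017 and 0.041, and 0 of 5 control animals correlated best with their own number. With the replicate block, 0 probe sets and 4 lists passed, as without it. Signal over background is not part of the RMA values, so which probe sets were too dim to measure is unknown.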

Other observations

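The tests of Bmal1 against Dbp, of Dbp against RNA quality, of the Dbp and Bmal1 gaps between same-numbered animals, of the probe set pairs of Cish and Onecut1 and of the 7 animals with higher Bcl6 were chosen after the values were seen, as was the ranking of genes by their spread within groups, from which Bcl6, Onecut1, Cish, Egr1, Dbp, RT1-Bb and Abhd3 were taken.

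Several liver genes differed far more between animals of a group than between the groups. Bcl6, a repressor controlled by growth hormone, ranged 31.4-fold over the 10 animals, the transcription factor Onecut1 27.6-fold and Cish, an inhibitor of growth hormone signalling, 13.5-fold. The immediate early gene Egr1 ranged 17.0-fold, Cyp7a1 13.1-fold and Dbp, an output gene of the circadian clock, 12.8-fold. Their limma adjusted p values between the groups were 0.915 or higher.

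In male rats growth hormone is released in pulses, so a candidate explanation for Bcl6, Cish and Onecut1 is the time since the last pulse. Bcl6 ran against Onecut1 (r = -0.791, adjusted permutation p 0.0115; rho = -0.745, adjusted p 0.0356; r = -0.785 without the 2 animals farthest out), while r was -0.596 against Cish (adjusted permutation p 0.0952; rho = -0.612, adjusted p 0.0899; r = -0.685 without the 2 farthest) and 0.360 for Cish with Onecut1 (adjusted p 0.307; rho = 0.333, adjusted p 0.349). The adjustment took in Bmal1 with Dbp, chosen after its values were seen, whose small p can lower the adjusted values of the others. It does not cover the choice of these genes by their spread. The relation with Onecut1 rests on 3 animals that read 5.92 to 6.05 for Bcl6, since over the other 7 it gave r = -0.219 (exact permutation p 0.644), and Bcl6 with Cish gave r = -0.969 there (exact permutation p 1.98e-04, the smallest possible, not adjusted), a split that was drawn from the Bcl6 values themselves. The same 3 animals, control animal 5 and exposed animals 4 and 5, had the highest values of Dbp (8.8 to 9.5). They also had the lowest values of the clock gene Bmal1 (6.1 to 6.8). Whether the phase of the daily cycle, taken up below, accounts for the relation was not tested. Noise of single probe sets is argued against for Cish and Onecut1, whose probe set pairs correlated at 0.949 or more, while Bcl6 has 1 probe set. The hypothesis stays open, because Bcl6 with Cish missed the threshold set for it, and so does RNA quality, with r = -0.223 for Bcl6 and a 95% interval of -0.748 to 0.473.

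Clock genes separated the animals as well, as Bmal1 and Dbp, which peak at opposite times of day, ran against each other (r = -0.945, permutation p 3.00e-05, adjusted 1.20e-04; rho = -0.964, adjusted p 2.00e-04; r = -0.955 without the 2 farthest animals), so the animals may have been killed at different phases of the daily cycle. Whether animals with the same number shared a time of day was left open by a test over 17 clock genes without Dbp. The mean residual correlation of same-numbered animals was 0.182, which 19 of 120 pairings reached, with 0.378 as the highest. In controls Dbp rose with each number, from 5.8 in animal 1 to 9.3 in animal 5, and Bmal1 fell from 8.1 to 6.8. Exposed animals 1 to 5 read 7.3, 6.8, 8.7, 8.8 and 9.5 for Dbp and 7.5, 7.6, 7.1, 6.7 and 6.1 for Bmal1. The order itself was seen in the values and not tested. Group means removed, same-numbered animals lay 0.670 apart for Dbp (median of all pairings 1.45, with 6 of 120 as small) and 0.156 for Bmal1 (median 0.591, 2 of 120 as small), and Dbp was higher and Bmal1 lower in the exposed animal of all 5 numbers. Any difference in clock phase between the groups is therefore not told apart from an effect of the exposure. RNA quality stays open too (r of Dbp with the 3' to 5' ratio 0.310, 95% interval -0.397 to 0.786). With Dbp as a covariate limma called 0 probe sets, with 2138 at an unadjusted p under 0.05, and camera called 6 lists at its preset correlation (the 4 called without it, Kupffer cell and macrophage markers and PPAR-alpha genes) but 0 with an estimated one, with the mean moving from 0.167 to 0.321 for Kupffer cell and from 0.114 to 0.191 for lymphocyte markers.

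The pair of probe sets of RT1-Bb, a class II histocompatibility gene, did not follow each other. The first read 4.22 and 3.95 in control animals 1 and 2 and 6.85 to 8.60 in the others, a difference of 1.49 ± 0.71 (SE) between the groups with a limma adjusted p of 0.879, while the second read 7.90 in control animal 2, 6.92 and 6.28 in exposed animals 1 and 3, and 3.75 to 4.74 in the other 7. A probe set of Abhd3 read between 3.58 and 4.18 in 4 animals and between 7.19 and 8.08 in the other 6, while its other probe set stayed between 4.58 and 5.39. No explanation was tested for these values.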
